A study of Rattus norvegicus with 12 samples.

How the data were processed

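RNA from the livers of male Sprague-Dawley rats was measured on 12 single-colour Affymetrix rat arrays, 3 arrays for each of 4 diets. Per the labels' protocols, rats that started at 150 g were overfed by 17% of calories for 21 days through total enteral nutrition, in which a liquid diet is infused into the stomach, with isocaloric diets of 5% or 70% fat made of corn oil or olive oil, in which the fat to carbohydrate ratio varied. Per the labels, each array held a pool of RNA, 8 ug of total RNA was labelled with biotin by in vitro transcription, and pools were numbered 1 to 3 within a diet. The number of rats in a pool is not given in the sources used here, so p-values measure the spread between pools. A further oil named in the protocol was not analysed here.

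The authors deposited log2 values for 8799 probe sets. Per the submitters' processing notes, GCOS and RMA were used, with no version given. RMA values are on a log2 scale; the base is not written in the table, and it was taken as 2. In the deposited table the median of each probe set over the 12 arrays was 0 within 1e-06 for 100% of probe sets, so each value is a difference from that probe set's median and no absolute level is known. Array medians ran from -0.0268 to 0.0622. There were 0 columns of other samples. Signal over background cannot be judged from centred values, and for arrays the number of arrays limits the precision.

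Of the probe sets, 59 array controls were left out and 8740 were tested. The platform annotation gave exactly 1 gene symbol to 7006 probe sets and several to 308, from which no gene was named, and 1426 were unnamed here. Through the gene identifier, 6985 of the named probe sets took the symbol of the GRCr8 annotation and 21 kept the older symbol. No positions are given, since the annotation was used for names alone. Of the 4736 genes, 1565 had more than 1 probe set.

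Tests used limma 3.58.1 in R 4.3.3. A linear model gave each diet a mean over its 3 arrays, all 12 arrays shared 1 estimate of the spread per probe set with 8 residual degrees of freedom, and variances were moderated by eBayes without a trend. The contrasts were 70% minus 5% fat with each oil, corn minus olive oil at each fat level, the difference between both fat effects (the interaction), and the means of both fat effects and of both oil effects. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Adjusted p-values given beside genes come from limma on 1 value per gene.

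The plan, written before the data were examined, was to represent a gene by its probe set with the highest mean. Centred values do not allow this choice, so a gene's value is the mean of its probe sets, which had been planned as the alternative. A filter on low values was planned and could not be applied for the same reason. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes. P-values were adjusted over the 29 lists fixed before the data were examined. Counts of members adjusted over the list alone are given for a part of the lists. The rule for named genes, fixed at the same time, took for each contrast the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap (for the interaction and the means, past the threshold alone), up to 4 members of each list past the threshold, up to 2 members with the smallest p in a list that had none, a set of genes always looked up, and the 5 smallest p-values where a contrast had no call. Symbols made only of numbers were skipped. The text names a part of these genes. Of the genes always looked up, Fgf21, Fads1 and Fads2 had no probe set with that symbol alone, and some others are not reported here.

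The 3'/5' index of an array is the mean, over actin and GAPDH, of the control probe set at the 3' end minus that at the 5' end of the transcript. It was chosen after the values had been seen, was compared between groups by exact permutation tests, and served as a covariate in an added alternative. Other alternatives were a second quantile normalization, centring of each array, a trend with robust moderation, array weights and the pool number as a block. Further ones were fits on the arrays of 2 groups, 1 value per gene, a 1.5-fold minimum and leaving out each array in turn. An estimated correlation and fry were used for the lists. Robust moderation without the trend was not planned. The second quantile normalization ran on the centred values, so it gave every array the same spread of differences from the medians. It did not repeat the normalization within RMA.

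The code was tested on simulated data with the residual spread of the real probe sets. In the corn oil fat contrast, with 8740 simulated probe sets, 74% of probe sets changed by 1.5-fold and 94% of those changed by 2-fold were recovered, with 10 false calls. In the olive oil fat contrast these shares were 54% and 86%, with 9 false calls. In the oil contrasts they were 64% and 86% at 70% fat, with 8 false calls, and 76% and 92% at 5% fat, with 7 false calls. A list shifted by 0.4 on the log2 scale in the olive oil fat contrast of 4736 simulated genes was called, with 0 of the other lists. Where 8740 simulated probe sets followed the 3'/5' index and no diet, the fit without the index called 3383 of them between oils at 70% fat and 5453 at 5% fat, and the fit with the index called 0 in both.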

Results

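Liver gene expression was measured on 12 arrays, each of a pool of RNA from rats overfed for 21 days on a liquid diet. The design crossed the oil, corn (rich in polyunsaturated fatty acids) or olive (rich in monounsaturated fatty acids), with its share, 5% or 70% fat, and held 3 arrays for each of the 4 diets. Per the labels the diets were isocaloric and their fat to carbohydrate ratio varied, so a fat effect here is also an effect of less carbohydrate. The comparisons address how the liver's transcripts differ with the level and with the type of dietary fat. Values are log2 differences from each probe set's median over the arrays, errors are standard errors of the model (SE) with 3 arrays per diet unless stated, and the number of arrays limits the precision. No pair of arrays was a duplicate: the closest pair differed by 0.195 log2 (root mean square).

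Control probe sets at the ends of the actin and GAPDH transcripts separated the oils. The 3'/5' index averaged 1.28 ± 0.28 (SD, n = 3) with 5% corn oil and 0.71 ± 0.48 (SD, n = 3) with 70% corn oil. It averaged -0.36 ± 0.06 (SD, n = 3) with 5% olive oil and -0.35 ± 0.10 (SD, n = 3) with 70% olive oil. The difference between the 6 corn and 6 olive oil arrays was 1.35 (exact permutation test, two-sided p = 0.00216). Pool 2 of 70% corn oil, at 0.16, was the corn oil array closest to the olive oil arrays. Between fat levels the index differed by -0.56 with corn oil (exact permutation p = 0.2) and by 0.018 with olive oil (exact permutation p = 0.8), where 3 arrays against 3 cannot give a p below 0.1. The first principal component held 48.6% of the variance, and within the 6 corn oil arrays it followed the index (Pearson r = -0.99, exact permutation p = 0.00417, adjusted 0.00833 over 2 relations; Spearman rho = -0.94, exact permutation p = 0.0167, adjusted 0.0333). Without the 2 arrays farthest from the median index r was -0.92. Within the 6 olive oil arrays r was -0.28 (exact permutation p = 0.59, adjusted 0.59) and rho was -0.14 (exact permutation p = 0.803, adjusted 0.803), with r at -0.88 without the 2 farthest arrays.

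**Figure D1:**
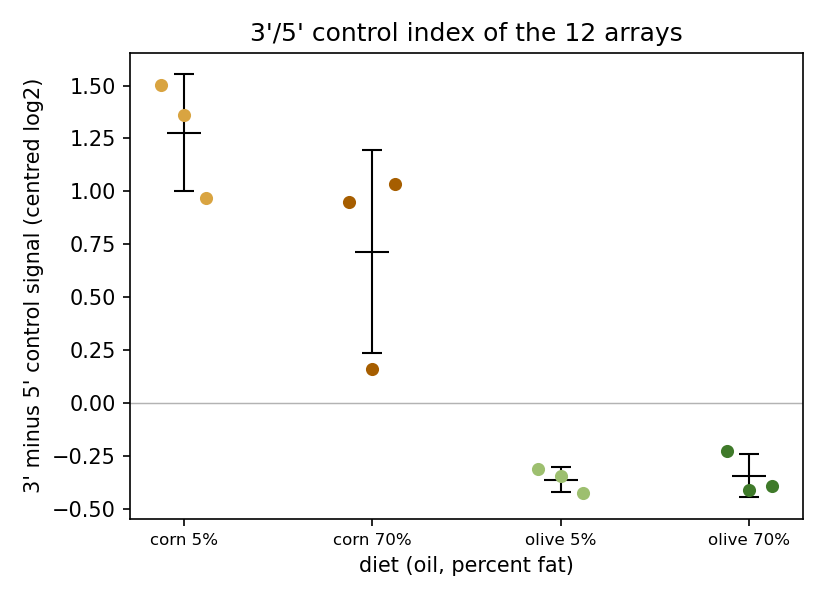
The vertical axis gives the 3'/5' index (3' minus 5' control signal, centred log2) and the horizontal axis the diet; points are the 12 arrays and bars the mean ± SD of 3 arrays. The 6 olive oil arrays lie below 0 and the 6 corn oil arrays above 0, with 1 corn oil array at 0.16.

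With corn oil, 5 of 11 measured genes of de novo lipogenesis fell at 70% fat and 11 of 34 measured genes of fatty acid oxidation and PPARA targets rose, on arrays whose 3'/5' index differed by -0.56 between the fat levels. Scd, the desaturase that makes monounsaturated fatty acids, was 46.5-fold lower (log2 change -5.54 ± 0.34, adjusted p = 4.82e-06). Pnpla3, which encodes a lipid droplet protein, was 25.6-fold lower (-4.68 ± 0.42, adjusted p = 0.000107). Of the 11 measured members of the list of de novo lipogenesis, 5 fell and 0 rose (6 fell when adjusted over the list alone), among them Fasn, the fatty acid synthase, at -1.45 ± 0.24 and Me1, the malic enzyme that supplies NADPH, at -1.15 ± 0.26. The 2 probe sets of Fasn differed in size, at -2.63 and -0.28. Fasn was at -1.60 and Me1 at -1.54 with the index as a covariate, each no longer past the test, and the call of Me1 was also lost without any 1 of 9 arrays. Srebf1, a regulator of these genes, was at 0.13 ± 0.24 (adjusted p = 0.819). The list shifted down (camera adjusted p = 8.82e-06; adjusted p = 0.38 with an estimated correlation).

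Of 9 measured members of glycolysis and the pentose phosphate pathway, 3 fell on the same arrays, with the same index difference of -0.56 (3 adjusted over the list alone): Pklr, the liver pyruvate kinase, by 2.11 ± 0.25, Khk, the fructokinase, by 0.90 ± 0.13, and Pfkfb1 by 0.57 ± 0.13. The call of Pfkfb1 was lost without any 1 of 8 arrays (adjusted p up to 0.111). Pfkfb1 was at -0.63 and Khk at -0.84 with the index as a covariate, and neither passed, with the SE of each at 0.17 against 0.13 before. That list had a camera adjusted p of 0.000319 (adjusted p = 0.393 with an estimated correlation). Of 9 measured genes of gluconeogenesis 0 passed by limma (2 fell adjusted over the list alone; camera adjusted p = 0.322). Outside these lists, the fructose transporter Slc2a5 fell by 1.22 ± 0.12 and Tkfc, which phosphorylates glyceraldehyde from fructose, fell by 1.26 ± 0.21, a call that was lost with the index, where Tkfc was at -1.19 with an SE of 0.28.

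Of 34 measured members of the list of fatty acid oxidation and PPARA targets, 11 rose and 0 fell with corn oil (18 rose and 1 fell when adjusted over the list alone), again with the index difference of -0.56. Acot1, an acyl-CoA thioesterase, was 9.72-fold higher (3.28 ± 0.64, adjusted p = 0.0191). Cyp4a1, a fatty acid omega-hydroxylase, rose by 1.81 ± 0.21, Ech1 by 1.58 ± 0.23, the peroxisomal carnitine acyltransferase Crot by 1.56 ± 0.29 and Cpt1a, which commits fatty acids to mitochondrial oxidation, by 1.42 ± 0.25. The calls of Acot1 and Crot were lost without pool 1 or 2 of 5% corn oil or pool 2 of 70% corn oil (adjusted p up to 0.0927 and 0.0705), and that of Cpt1a without pool 1 of 5% corn oil (adjusted p = 0.0614). Acot1 was at 2.32, Crot at 1.20, Ech1 at 1.28 and Cpt1a at 1.65 with the index as a covariate, each no longer past the test; Cyp4a1 and Ech1 kept the call without each array in turn. The list shifted up (camera adjusted p = 3.29e-12; adjusted p = 0.0756 with an estimated correlation). Pdk4 (0.46 ± 0.22, adjusted p = 0.275) and the fatty acid transporter Cd36 (0.23 ± 0.20, adjusted p = 0.59) did not pass the test.

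Among 15 measured genes of fatty acid uptake and lipid droplets, Cidea rose by 1.41 ± 0.24, while Fabp5 fell by 2.51 ± 0.24, Apoa4 by 1.22 ± 0.17 and Fabp4 by 0.35 ± 0.08 (3 rose and 3 fell adjusted over the list alone); the list did not shift (camera adjusted p = 0.573). Of 21 measured drug and steroid metabolising cytochromes 5 rose (6 rose and 1 fell adjusted over the list alone), including Cyp2b2 by 1.15 ± 0.24, Cyp2e1 by 1.08 ± 0.25 and Cyp2a1 by 0.88 ± 0.15, without a shift of the list (camera adjusted p = 0.246, with a median of -0.0073 and a mean of 0.13). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 0.74 ± 0.17. The endoplasmic reticulum chaperone Hspa5 fell by 0.52 ± 0.12 and its partner Dnajb9 by 1.01 ± 0.17, 2 of the 13 measured genes of endoplasmic reticulum stress (3 adjusted over the list alone), a list that did not shift (camera adjusted p = 0.11). Among the other largest changes, Serpina7, which encodes a thyroxine-binding protein, rose by 2.37 ± 0.33, the mitochondrial carrier Slc25a30 by 2.13 ± 0.50, Adh1c by 1.69 ± 0.30 and Aldh1a1 by 1.55 ± 0.14, and Nupr1 fell by 1.35 ± 0.32. Oxidative phosphorylation shifted down as a list of 27 genes (camera adjusted p = 0.000621; adjusted p = 0.743 with an estimated correlation), with 1 member past the test (3 adjusted over the list alone), Cox6c at -1.10 ± 0.25, whose 2 probe sets lay at -2.19 and -0.01. Tnf (0.05 ± 0.11, adjusted p = 0.856) and Col1a1 (-0.20 ± 0.13, adjusted p = 0.455) did not pass the test. Of the genes in this paragraph Apoa4, Fabp5, Serpina7, Aldh1a1 and Cyp2a1 kept the call without each array in turn. The call was lost without any 1 of 11 arrays for Fabp4, 9 for Slc25a30, Cyp2e1 and Hspa5, 8 for Cyp7a1, Nupr1 and Cox6c, 5 for Cyp2b2, 2 for Adh1c and 1 for Cidea and Dnajb9 (adjusted p up to 0.1635). Apoa4, Fabp5, Serpina7, Aldh1a1 and Dnajb9 were still called with the index as a covariate. The other calls in the paragraph ended in that fit. There Cidea was at 1.17, Fabp4 at -0.39, Cyp2b2 at 0.70, Cyp2e1 at 0.84, Cyp2a1 at 0.64, Cyp7a1 at -0.61, Hspa5 at -0.52, Slc25a30 at 1.72, Adh1c at 1.13, Nupr1 at -0.83 and Cox6c at -0.46. Probes of the Scd, Cyp2b, Cyp2c and Cyp4a families can bind related transcripts.

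In all, 184 of 8740 probe sets changed with fat level under corn oil, 114 up and 70 down, and 120 of 4736 genes, 72 up and 48 down. With the 3'/5' index as a covariate, 40 probe sets and 23 genes passed, and a second quantile normalization gave 51 probe sets, 26 up and 25 down. Fits on the arrays of 1 oil alone gave 53 probe sets with corn oil and 97 with olive oil, where 38 changed with the shared spread. Which oil had the higher count thus depended on the fit. With the spread shared, olive oil also had the higher count after a second quantile normalization (98 against 51) and with the index (64 against 40). With array weights the counts were 138 and 137. Corn oil had the higher count in the other settings, among them each array centred (170 against 22) and the block of pool numbers (221 against 37). Of 35 named genes called with corn oil 25 lost the call with the index; their median ratio of the change with to without it was 0.82, and their median SE went from 0.2405 to 0.2611. The second quantile normalization ended the calls of 24 of the 35 (adjusted p up to 0.352), among them Fasn, Apoa4, Tkfc, Crot, Ech1, Cpt1a, Serpina7 and Cyp2a1. That step ran on centred values and made the spread of every array equal. Array weights ended 14, the trend together with robust moderation 13, among them Acot1, centring each array 11 and the block of pool numbers 8. Scd, Pnpla3, Pklr, Khk, Fabp5, Slc2a5, Cyp4a1, Aldh1a1, Adh1c and Dnajb9 kept theirs under these 5 settings. The count was 59, 68 and 348 without pools 1, 2 and 3 of 5% corn oil, and 311 and 83 without pools 1 and 2 of 70% corn oil. It was 121 without pool 2 of 5% olive oil, and 111 and 110 without pools 1 and 2 of 70% olive oil.

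With olive oil, the fall of lipogenic genes and the rise of oxidation genes were also measured, on arrays whose index did not differ between fat levels beyond 0.018. Pnpla3 was 25.0-fold lower at 70% fat (-4.64 ± 0.42, adjusted p = 0.000233), Scd 6.22-fold lower (-2.64 ± 0.34, adjusted p = 0.00389) and Fasn 4.83-fold lower (-2.27 ± 0.24, adjusted p = 0.000891). Acly, which makes cytosolic acetyl-CoA, fell by 0.93 ± 0.14. Of 11 lipogenic genes 5 fell (9 adjusted over the list alone), and the list shifted down (camera adjusted p = 1.2e-19; adjusted p = 0.0131 with an estimated correlation). Srebf1 was at 0.06 ± 0.24 (adjusted p = 0.976). Pklr fell by 1.30 ± 0.25 and was the 1 glycolytic gene of 9 past the test (4 adjusted over the list alone), a call lost without any 1 of 8 arrays (adjusted p up to 0.218); that list had a camera adjusted p of 2.16e-06 (adjusted p = 0.133 with an estimated correlation). Fabp5 fell by 3.06 ± 0.24, Apoa4 by 1.08 ± 0.17 and Slc2a5 by 0.87 ± 0.12. Acly and Apoa4 each lost the call without any 1 of 2 arrays (adjusted p up to 0.063).

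Of 34 oxidation genes and PPARA targets 6 rose with olive oil (15 adjusted over the list alone), and the list shifted up (camera adjusted p = 9.25e-21; adjusted p = 0.0131 with an estimated correlation). Acot1 was 13.0-fold higher (3.70 ± 0.64, adjusted p = 0.0228). Crot rose by 1.56 ± 0.29, Cyp4a1 by 1.11 ± 0.21, Pex11a, which acts in peroxisome division, by 1.03 ± 0.20, Eci1 by 0.90 ± 0.10 and Cpt2 by 0.57 ± 0.11. Eci1 kept the call without each array in turn. Without 1 array the call was lost for 4 arrays for Acot1, 9 each for Crot, Pex11a and Cpt2 and 10 for Cyp4a1, with adjusted p up to 0.218. The 4 probe sets of Eci1 ran from 0.15 to 1.61. Cpt1a (0.56 ± 0.25, adjusted p = 0.595), Pdk4 (0.38 ± 0.22, adjusted p = 0.715) and Cd36 (0.06 ± 0.20, adjusted p = 0.972) did not pass. Aldh1a1 rose by 1.04 ± 0.14, Cyp2b2 by 1.33 ± 0.24, the oxysterol hydroxylase Cyp7b1 by 0.72 ± 0.13 and Impa2 by 0.61 ± 0.12. Apobec1, the editing enzyme of apolipoprotein B mRNA, fell by 0.97 ± 0.15 and the lysosomal protease Ctss by 0.96 ± 0.16. The call was lost without any 1 of 8 arrays for Impa2 and Cyp7b1, 6 for Cyp2b2, 4 for Ctss and 3 for Apobec1, with adjusted p up to 0.218, and Aldh1a1 kept it without each array in turn. Cyp7a1 was at -0.72 ± 0.17 (adjusted p = 0.132, past the test after a second quantile normalization or with array weights) and Cyp2e1 at 0.70 ± 0.25 (adjusted p = 0.391). Tnf was at -0.08 ± 0.11 (adjusted p = 0.92) and Col1a1 at 0.36 ± 0.13 (adjusted p = 0.417).

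Several lists shifted with olive oil by camera with 0 members, or for the cytochromes 1 member, past the test over all genes. Cholesterol synthesis shifted down (15 genes, median -0.34, camera adjusted p = 6.66e-06; adjusted p = 0.314 with an estimated correlation; 3 fell adjusted over the list alone). Macrophage and Kupffer cell markers shifted down (9 genes, median -0.42, camera adjusted p = 6.24e-06; adjusted p = 0.133 with an estimated correlation; 6 fell adjusted over the list alone). The interferon response shifted down (11 genes, median -0.27, camera adjusted p = 6.24e-06; adjusted p = 0.178 with an estimated correlation). So did endoplasmic reticulum stress (13 genes, median -0.22, camera adjusted p = 0.00112; adjusted p = 0.228 with an estimated correlation) and endothelial markers (6 genes, median -0.22, camera adjusted p = 0.00931; adjusted p = 0.228 with an estimated correlation). Cell cycle genes shifted up (16 genes, median 0.12, camera adjusted p = 0.000498; adjusted p = 0.184 with an estimated correlation). The cytochromes shifted up too (21 genes, median 0.09, camera adjusted p = 0.0379; adjusted p = 0.432 with an estimated correlation), of which 1 rose (3 adjusted over the list alone).

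Under olive oil 38 probe sets changed, 11 up and 27 down, and 26 genes, 10 up and 16 down. Robust moderation without the trend, which was not planned, called 17 genes, all of them among the 26. Array weights gave 138 probe sets, fitting the arrays of both groups alone gave 97, a second quantile normalization 98, and centring each array 22, of which 4 were up and 18 down. Of 20 named genes 10 lost the call in at least 1 planned setting besides leaving out an array. With each array centred these were Pklr, Crot, Cyp4a1, Pex11a, Cpt2, Cyp2b2, Cyp7b1 and Impa2 (adjusted p up to 0.0863). Acot1 lost it with the trend and robust moderation together (adjusted p = 0.132) and Apoa4 after a second quantile normalization (adjusted p = 0.0537). The count was 12 and 13 without pools 1 and 3 of 5% olive oil, and 10 and 19 without pools 1 and 2 of 70% olive oil. It was 22 and 23 without pools 2 and 3 of 5% corn oil, and 69 and 61 without pools 2 and 3 of 70% corn oil.

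The fat effects under the oils were set against each other on arrays that shared no sample. Both contrasts share the estimate of the spread, so the lists of calls are not independent. The counts given for independent lists are thus only a guide. Of the genes that rose, 72 with corn and 10 with olive oil, 9 were shared, against 0.152 for independent lists: Acot1, Aldh1a1, Cpt2, Crot, Cyp2b2, Cyp4a1, Eci1, Impa2 and Pex11a. Of those that fell, 48 and 16, 9 were shared, against 0.162: Acly, Apoa4, Dlat, Fabp5, Fasn, Pklr, Pnpla3, Scd and Slc2a5. Dlat lies outside the rule for named genes and was named after its values had been seen. No gene was called in opposite directions. Across the 4736 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.451 and Spearman rho = 0.105. Of the genes called with olive oil, 23 of 26 had the same sign with corn oil, and of those called with corn oil, 103 of 120 had the same sign with olive oil.

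**Figure D2:**
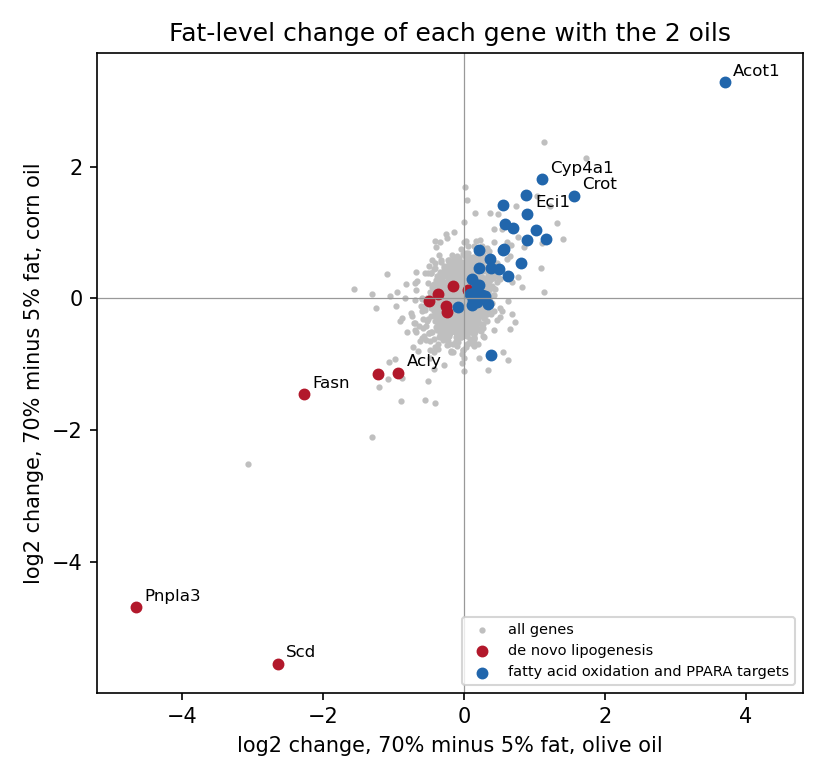
Each point is a gene; the horizontal axis is its log2 change from 5% to 70% fat with olive oil and the vertical axis that with corn oil, with the lipogenesis list in red and the list of oxidation genes and PPARA targets in blue. Pnpla3 lies at -4.64 and -4.68 and Acot1 at 3.70 and 3.28, while Scd fell further with corn oil (-5.54) than with olive oil (-2.64), a difference that did not pass the interaction test.

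**Figure D3:**
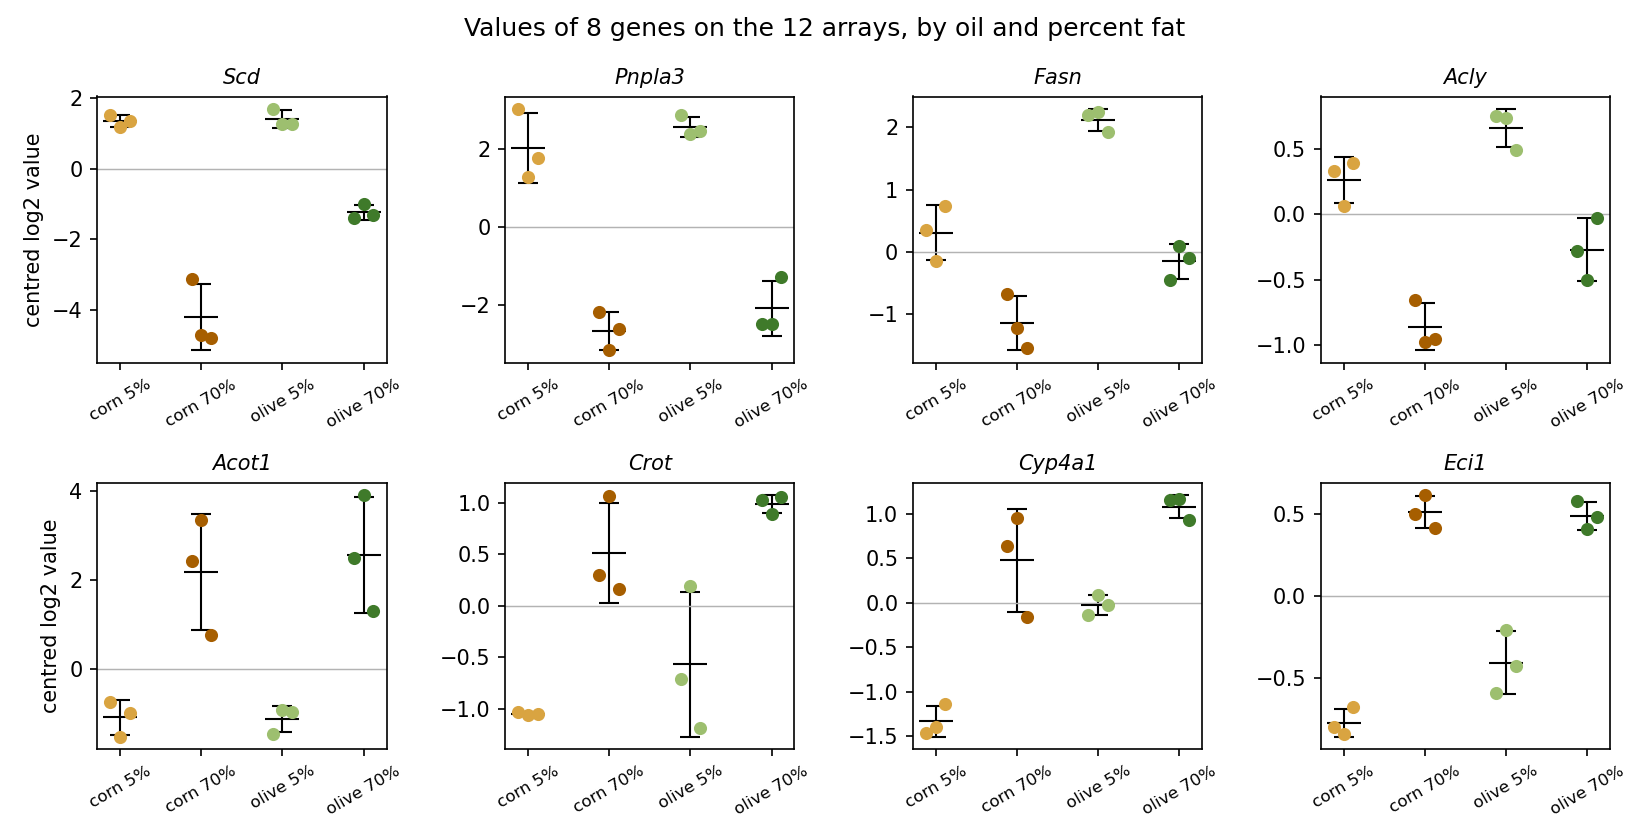
The vertical axes give centred log2 values and the horizontal axes the diet; points are arrays and bars the mean ± SD of 3 arrays. Scd, Pnpla3, Fasn and Acly were lower and Acot1, Crot, Cyp4a1 and Eci1 higher at 70% than at 5% fat with each oil.

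Averaged over both oils, these genes fell: Scd (-4.09 ± 0.24), Pnpla3 (-4.66 ± 0.30), Fabp5 (-2.785 ± 0.17), Fasn (-1.86 ± 0.17), Pklr (-1.71 ± 0.17), Me1 (-1.18 ± 0.18), Acly (-1.03 ± 0.10) and Khk (-0.69 ± 0.09). Acot1 rose by 3.49 ± 0.45, Serpina7 by 1.75 ± 0.23, Crot by 1.56 ± 0.20, Cyp4a1 by 1.46 ± 0.15, Aldh1a1 by 1.30 ± 0.10, Ech1 by 1.23 ± 0.16, Cpt1a by 0.99 ± 0.18 and Cyp2e1 by 0.89 ± 0.18, and Cyp7a1 fell by 0.73 ± 0.12. In this average 6 of 11 lipogenic genes fell (8 adjusted over the list alone; camera adjusted p = 1.24e-14, and 0.0332 with an estimated correlation). Of 34 oxidation genes and PPARA targets 16 rose (22 adjusted over the list alone; camera adjusted p = 6.44e-22, and 0.0119 with an estimated correlation). Of 9 glycolytic genes 3 fell (6 adjusted over the list alone; camera adjusted p = 2.1e-07; adjusted p = 0.107 with an estimated correlation). Cytochromes shifted up (4 of 21 rose; camera adjusted p = 0.0377; adjusted p = 0.5 with an estimated correlation). Macrophage markers shifted down (0 of 9 fell; camera adjusted p = 0.0396; adjusted p = 0.444 with an estimated correlation). The interferon response shifted down (0 of 11 fell; camera adjusted p = 0.00053; adjusted p = 0.405 with an estimated correlation). Endoplasmic reticulum stress shifted down (2 of 13 fell; camera adjusted p = 0.000884; adjusted p = 0.405 with an estimated correlation). Oxidative phosphorylation shifted down (0 of 27 fell; camera adjusted p = 0.000612; adjusted p = 0.444 with an estimated correlation). Both the lipogenic and the oxidation list held with an estimated correlation here and with olive oil, and no other list did in any contrast. The index as a covariate together with an estimated correlation left both lists with olive oil and the oxidation list here (adjusted p = 0.0412), while the lipogenic list here no longer passed (adjusted p = 0.0727). In total 199 probe sets changed, 109 up and 90 down, and 103 genes, 51 up and 52 down; with the index as a covariate 123 probe sets passed. The count was 116 without pool 2 of 5% corn oil, and 129 and 119 without pool 1 of 5% and of 70% olive oil.

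At 70% fat, several lipid genes were lower with corn than with olive oil, on arrays whose 3'/5' index differed by 1.06 between the oils. Scd was 7.79-fold lower (-2.96 ± 0.34, adjusted p = 0.00194), Cd36 2.38-fold lower (-1.25 ± 0.20, adjusted p = 0.00751), and Fasn was at -0.99 ± 0.24, Acly at -0.59 ± 0.14 and Acaca, the acetyl-CoA carboxylase, at -0.43 ± 0.07, each past the test. Of 11 lipogenic genes 4 were lower (7 adjusted over the list alone; camera adjusted p = 2.22e-06; adjusted p = 0.548 with an estimated correlation). With the index as a covariate Scd was at -3.56 ± 0.63 and Cd36 at -1.25 ± 0.39, and neither passed, nor did Fasn (-0.71), Acly (-0.69), Acaca (-0.55) or Apoa4 (-0.76). Fasn and Acly lost the call without any 1 of 4 and of 3 arrays (adjusted p up to 0.104). Apoa4 was lower by -0.89 ± 0.17 and Srebf1 was at -0.87 ± 0.24 (adjusted p = 0.0515). Srebf1 was past the test after a second quantile normalization, with the trend and robust moderation together, or with array weights.

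Of 34 oxidation genes and PPARA targets, 6 were lower and 1 higher with corn oil at 70% fat (9 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.00356; adjusted p = 0.69 with an estimated correlation). Pdk4 was at -1.03 ± 0.22, Acot2 at -1.01 ± 0.18 and Hadhb, a subunit of the mitochondrial trifunctional protein, at -1.23 ± 0.33, which became 0.36 ± 0.36 with the index as a covariate. Of 23 antioxidant and NRF2 target genes 3 were lower (3 adjusted over the list alone), Gclc at -1.40 ± 0.35, Gsr at -0.64 ± 0.15 and Sod1 at -0.52 ± 0.12 (camera adjusted p = 0.00356; adjusted p = 0.69 with an estimated correlation). Of 21 cytochromes 3 were lower (4 adjusted over the list alone), among them the male-specific Cyp2c11 at -1.56 ± 0.34 (camera adjusted p = 0.0119; adjusted p = 0.726 with an estimated correlation). Mug1, a plasma protease inhibitor, was at -2.47 ± 0.57 and the methionine adenosyltransferase Mat1a at -1.46 ± 0.24. In the same fit Mug1 turned to 0.20 and Gsr to 0.0051, and Mat1a was at -0.29, Cyp2c11 at -0.04, Gclc at -0.22, Acot2 at -0.26, Sod1 at -0.47 and Pdk4 at -0.85, none past the test. Without any 1 of 11 arrays Hadhb lost the call, as did Gclc for 6, Gsr and Cyp2c11 for 5, Mug1 for 4 and Pdk4 and Sod1 for 3 (adjusted p up to 0.124). These groups all lie on arrays that differed in the index.

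Higher with corn oil at 70% fat were the mitochondrial carrier Slc25a23 (1.14 ± 0.12), Rpl19l4 (1.11 ± 0.28), the endothelial marker Lyve1 (1.09 ± 0.20), Acat2 (0.97 ± 0.26), Igfbp3 (0.92 ± 0.22), the MHC class II chaperone Cd74 (0.69 ± 0.14) and the collagen gene Col1a2 (0.52 ± 0.13). None of these passed with the index as a covariate, where Slc25a23 was at 0.92, Rpl19l4 at 0.21, Lyve1 at 0.84, Acat2 at 0.93, Igfbp3 at 0.71, Cd74 at 0.75 and Col1a2 at -0.05. The median SE of the 22 named genes called at 70% fat went from 0.2071 to 0.366 in that fit. Acat2 lost the call without any 1 of 8 arrays, Col1a2 for 7, and Igfbp3 and Rpl19l4 for 5 (adjusted p up to 0.156). The cholesterol synthesis list of 15 genes, of which Acat2 passed (5 higher adjusted over the list alone), shifted up (camera adjusted p = 0.0389; adjusted p = 0.765 with an estimated correlation). That call was lost without pool 1 or 3 of 5% corn oil, pool 1 or 2 of 70% corn oil, or pool 1 or 2 of 70% olive oil (adjusted p up to 0.504). Tnf (0.12 ± 0.11, adjusted p = 0.585), Col1a1 (0.16 ± 0.13, adjusted p = 0.531) and Cyp2e1 (-0.09 ± 0.25, adjusted p = 0.893) did not pass. In all 744 probe sets differed, 346 higher and 398 lower with corn oil, and 328 genes, 162 higher and 166 lower. With the index as a covariate limma called 0 probe sets (698 at an unadjusted p under 0.05, where chance gives 437) and 1 gene. Fasn, Acly, Apoa4, Hadhb, Sod1, Mug1, Acat2, Col1a2 and Rpl19l4 lost the call in at least 1 planned setting besides leaving out an array (adjusted p up to 0.146). The count was 350, 1162 and 412 without pools 1, 2 and 3 of 70% corn oil, and 322, 373 and 311 without those of 70% olive oil.

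At 5% fat, where the index differed by 1.64 between the oils, Mug1 was 12.2-fold lower with corn oil (-3.61 ± 0.57, adjusted p = 0.00145), Mat1a 6.11-fold lower (-2.61 ± 0.24, adjusted p = 0.000132), the plasminogen gene Plg 5.81-fold lower (-2.54 ± 0.42, adjusted p = 0.00178) and Cyp2c7 5.36-fold lower (-2.42 ± 0.28, adjusted p = 0.000363). In the fit with the index as a covariate Mug1 turned to 0.53, and Mat1a was at -0.81, Plg at -0.03 and Cyp2c7 at -0.58, none past the test. Lipogenic genes were lower: Fasn at -1.81 ± 0.24, with probe sets at -3.13 and -0.50, Srebf1 at -0.95 ± 0.24 and Acaca at -0.88 ± 0.07, with 6 of 11 members past the test (8 adjusted over the list alone; camera adjusted p = 9.36e-06; adjusted p = 0.495 with an estimated correlation). Scd was at -0.06 ± 0.34 (adjusted p = 0.925). Cd36 was lower at -1.43 ± 0.20. Of 34 oxidation genes and PPARA targets 11 were lower and 2 higher (15 and 2 adjusted over the list alone), including Hadhb at -1.77 ± 0.33, Cyp4a1 at -1.31 ± 0.21 and Pdk4 at -1.11 ± 0.22 (camera adjusted p = 0.00156; adjusted p = 0.509 with an estimated correlation). Hadhb turned to 0.68 and Cyp4a1 to 0.009 with the index as a covariate, where Fasn was at -1.38, Acaca at -1.055, Cd36 at -1.42, Pdk4 at -0.83 and Srebf1 at -0.18, none past the test. Srebf1 also lost the call without any 1 of 3 arrays (adjusted p up to 0.079).

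Of 27 genes of amino acid catabolism and the urea cycle 8 were lower and 2 higher with 5% corn oil (10 and 3 adjusted over the list alone), with Cps1 at -0.78 ± 0.13 over 3 probe sets that ran from -2.52 to 0.14 (camera adjusted p = 0.00156; adjusted p = 0.611 with an estimated correlation). Gclc was at -2.11 ± 0.35 among 23 antioxidant genes, 4 of them lower (5 adjusted over the list alone; camera adjusted p = 0.0412; adjusted p = 0.611 with an estimated correlation). Of 15 hepatocyte markers 5 were lower and 2 higher (5 and 2 adjusted over the list alone), with Apoa1 at -0.60 ± 0.15 and Hnf4a at -0.44 ± 0.11 (camera adjusted p = 0.0407; adjusted p = 0.495 with an estimated correlation). Of 23 stellate cell and matrix genes 7 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.0407; adjusted p = 0.599 with an estimated correlation), with Vim at 1.05 ± 0.17, Col1a2 at 0.80 ± 0.13, Col1a1 at 0.72 ± 0.13 and Dcn at 0.70 ± 0.13. Cps1 turned to 0.0319, Hnf4a to 0.22 and Col1a2 to -0.0894 with the index as a covariate, where Gclc was at -0.30, Apoa1 at -0.54, Vim at 0.05, Col1a1 at 0.17 and Dcn at 0.21, none past the test. Hnf4a lost the call without any 1 of 3 arrays and Apoa1 without pool 3 of 5% olive oil (adjusted p up to 0.0723). The 4 probe sets of Col1a1 ran from 0.18 to 2.29. All of these groups moved on arrays whose index differed by 1.64.

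Other genes higher with 5% corn oil were Rpl19l4 (2.01 ± 0.28), Cyp2c12 (1.85 ± 0.44), Ugt2b37 (1.38 ± 0.22), Cyp7b1 (1.02 ± 0.13), Igfbp3 (0.93 ± 0.22) and Lyve1 (0.89 ± 0.20). In the fit with the index Rpl19l4 was at 0.62, Cyp2c12 at 1.52, Ugt2b37 at 2.16, Cyp7b1 at 1.47, Igfbp3 at 0.62 and Lyve1 at 0.50, none past the test, and the median SE of the 25 named genes called at 5% fat went from 0.2166 to 0.5289. Cyp2c12 lost the call without any 1 of 2 arrays and Igfbp3 without pool 1 of 5% corn oil (adjusted p up to 0.0532). Tnf (-0.01 ± 0.11, adjusted p = 0.985) and Cyp2e1 (-0.48 ± 0.25, adjusted p = 0.223) did not pass, though Cyp2e1 did with array weights. In all 1704 probe sets differed, 886 higher and 818 lower with corn oil, and 801 genes, 399 higher and 402 lower. With the index as a covariate limma called 0 probe sets (522 at an unadjusted p under 0.05) and 0 genes, and 1115 probe sets differed without pool 2 of 5% olive oil. Of 169 genes with at least 2 probe sets called at 5% fat, 54 had probe sets called in opposite directions, against 5 of 57 between oils at 70% fat and 0 of 18 in the fat contrast with corn oil.

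Of the genes that differed between oils, 101 were higher with corn oil at both fat levels, against 13.6 for independent lists, and 134 were lower, against 14.1. These contrasts share no array, but they share the estimate of the spread, and both carry the difference in the index. Averaged over both fat levels 2120 probe sets differed, 1147 higher and 973 lower, and 1035 genes, 564 higher and 471 lower. In this average 9 of 11 lipogenic genes were lower (9 adjusted over the list alone; camera adjusted p = 1.9e-07; adjusted p = 0.384 with an estimated correlation). Also lower were 13 of 34 oxidation genes, with 1 higher (camera adjusted p = 0.000454; adjusted p = 0.488 with an estimated correlation), and 7 of 23 antioxidant genes (camera adjusted p = 0.00663; adjusted p = 0.488 with an estimated correlation). So were 9 of 27 amino acid genes, with 5 higher (camera adjusted p = 0.00748; adjusted p = 0.671 with an estimated correlation), and 7 of 21 cytochromes, with 1 higher (camera adjusted p = 0.0149; adjusted p = 0.536 with an estimated correlation). With the index as a covariate limma called 0 probe sets (579 at an unadjusted p under 0.05) and 0 genes. In that fit the lipogenic list stayed lower, with a median of -0.54 against -0.64 (camera adjusted p = 0.00503; adjusted p = 0.764 with an estimated correlation). Bile acid synthesis, macrophage markers and oxidative phosphorylation, not called without the index, were higher there (camera adjusted p = 0.000691, 0.0269 and 0.00377; adjusted p = 0.498, 0.764 and 0.764 with an estimated correlation). In simulated data such a fit recovered 92.5% of 200 probe sets given a 4-fold difference between the oils. The share was 96% at 70% fat and 82.5% at 5% fat. Those data held independent noise and 200 equally large changes, so they do not show that such a difference would be called here. Scd at 70% fat, at -3.56 ± 0.63 with the index, did not pass.

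The fat effects under both oils were compared by the interaction, in which limma called 0 of 8740 probe sets and 0 of 4736 genes at the threshold (1028 probe sets and 565 genes at an unadjusted p under 0.05, where chance gives 437 probe sets). Without pool 3 of 5% corn oil it called 10, and without pool 1 of 70% corn oil 3. The genes with the smallest p were Scd, whose change with corn oil was lower than that with olive oil by -2.90 ± 0.48 (adjusted p = 0.168; -1.2523 after a second quantile normalization, adjusted p = 0.0768), Cyp7b1 (-1.08 ± 0.18, adjusted p = 0.168), Cavin3 (0.84 ± 0.16, adjusted p = 0.205), Epb41l4b (0.87 ± 0.17, adjusted p = 0.205) and Ugt2b37 (-1.56 ± 0.31, adjusted p = 0.205). Lists of cholesterol synthesis, macrophage markers, cell cycle and amino acid catabolism differed between the oils by camera, with 0 members past the test over all genes, on arrays whose index differed between fat levels by -0.56 with corn and 0.018 with olive oil. Adjusted over the list alone, 2 cholesterol genes and 3 macrophage markers were higher and 2 cell cycle genes lower in the difference. The adjusted p-values with an estimated correlation were 0.921, 0.595, 0.595 and 0.961, so that none passed.

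In these lists, which did not shift with fat level under either oil by camera, 0 members passed by limma: gluconeogenesis (0 of 9 genes with each oil), ketone body synthesis (0 of 4), desaturation and elongation of polyunsaturated fatty acids (0 of 2), antioxidant genes (0 of 23), inflammatory cytokines and acute phase (0 of 28), matrix genes (0 of 23), the circadian clock (0 of 9), insulin and growth factor signalling (0 of 18), hepatocyte markers (0 of 15), bile duct markers (0 of 6), T and NK cell markers (0 of 15), the B cell list (0 of 1), neutrophil markers (0 of 7), red blood cell markers (0 of 3) and adipose and pancreas markers (0 of 12). Bile acid synthesis and amino acid catabolism did not shift under either oil. In bile acid synthesis 1 of 14 genes fell with corn oil and 1 rose with olive oil. In amino acid catabolism 2 of 27 rose with corn oil, Mat1a by 1.01 ± 0.24 and Agxt by 0.47 ± 0.10, and Glul fell by 0.38 ± 0.09. Among the 6 endothelial markers, which shifted with olive oil and not with corn oil (camera adjusted p = 0.507), Kdr fell by 0.65 ± 0.15 with corn oil. The calls were lost without any 1 of 10 arrays for Mat1a, 6 for Agxt, 11 for Glul and 8 for Kdr (adjusted p up to 0.163). Each was also lost with the index as a covariate, where Mat1a was at 0.39, Agxt at 0.39, Glul at -0.34 and Kdr at -0.74.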

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

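The index, its use as a covariate, the slope test in the reverse direction and the tests of the dietary oil itself and of the fat-level changes were chosen after the values had been seen.

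The array controls, which the comparisons do not use, carried a signal: the 3'/5' index was 1.35 higher on corn oil than on olive oil arrays, so the probe sets that differed between the oils were examined for signal lost toward the 5' end. The corn minus olive difference was compared in 83 genes with both a coding-sequence probe set and a 3' EST probe set. It was lower at the coding sequence by a median of -0.284 (72 of 83 genes, sign-flip permutation p = 1e-04, the smallest 10000 permutations can give). That p measures the spread between genes, which share the same 12 arrays and are not independent replicates. It does not measure the spread between pools. A change in a gene's RNA should move both probe sets alike, and the same median was -0.007 in the olive oil fat contrast. A part of the oil difference may thus be lost 5' signal. Across 8740 probe sets the slope on the index among the 5% corn oil arrays correlated with the oil difference at 70% fat, which shares no array with it, at r = 0.261, which lies between the bounds set beforehand (above 0.3, or under 0.1) and decides nothing; the slope among the 70% corn oil arrays correlated with the oil difference at 5% fat at r = 0.495, for which no bound had been set. An effect of the oil itself cannot be told apart from it, because every olive oil array has a low index: with it as a covariate 1 gene was called at 70% or 5% fat, camera called 4 lists at each level and averaged, and 0 with an estimated correlation, while the median SE of the named genes called without it went from 0.2071 to 0.366 at 70% fat and from 0.2166 to 0.5289 at 5% fat, so that wider errors ended calls as well as smaller changes. The lipogenic list was lower with corn oil with and without the index at 70% fat, at 5% fat and averaged (with it adjusted p = 0.00488, 0.0251 and 0.00503; adjusted p = 0.734, 0.795 and 0.764 with an estimated correlation), cholesterol synthesis was higher in both fits at 70% fat (with it adjusted p = 0.000724; adjusted p = 0.734 with an estimated correlation), and Scd at 70% fat went from -2.96 ± 0.34 to -3.56 ± 0.63 (adjusted p = 0.2495), so the explanations stay open for large changes too.

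The fat-level changes shared by both oils were weighed against the same explanation. Of the 18 genes called with each oil, 11 were also called with each oil when the index was a covariate. With corn oil their median absolute log2 change was 1.55 before and 1.36 after. This argues against lost 5' signal, as far as the index tracks it, as the whole cause for these 11. With olive oil the index differed by 0.018 between fat levels, which argues against lost 5' signal as the whole cause of that change. There the covariate could hardly move a change, so the 18 of 18 genes still called with it add no evidence. Lost 5' signal stays open for the change of the other 7 with corn oil. Their median went from 1.15 to 0.78 and their median standard error from 0.241 to 0.259. Of the 102 genes called with corn oil alone 10 were called with the index. For these 10 that argues against lost 5' signal as the whole cause only as far as the index tracks it. The index rests on actin and GAPDH, so loss that it does not track stays open for them too. Lost 5' signal stays open for the others. Their median ratio of adjusted to unadjusted change was 0.911, while the median standard error rose from 0.122 to 0.154. A call with corn oil alone does not show a difference between the oils, since the interaction called 0 genes. In the corn oil fat contrast the coding-sequence probe sets did move above the EST probe sets, by a median of 0.161. At the coding sequence 26 of 83 genes were lower (sign-flip permutation p = 1e-04, again over genes). Less lost 5' signal at 70% fat, where the index differed by -0.56, would give this direction. Lost 5' signal may thus be a part of this contrast as a whole. Its share in any 1 gene was not measured, and a dietary effect is untested beyond the contrasts themselves.

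The fat effect differed between the oils, by the interaction, for 4 gene lists at a preset correlation. The camera adjusted p was 0.000149 for cholesterol synthesis, 0.00333 for macrophage and Kupffer cell markers, 0.00333 for cell cycle and 0.0244 for amino acid catabolism. With an estimated correlation none passed (adjusted p = 0.921, 0.595, 0.595 and 0.961). The amino acid call was also lost without pool 1 of 5% corn oil, pool 1 or 2 of 5% olive oil, pool 1 or 2 of 70% corn oil, or pool 1 or 3 of 70% olive oil (adjusted p up to 0.504). The members with the smallest p were Acat2 (1.47 ± 0.37) and Lss (0.63 ± 0.18), Lgals3 (0.87 ± 0.19) and C1qb (0.93 ± 0.25), Ccnd1 (-0.59 ± 0.14) and Ccnb1 (-0.35 ± 0.11), and Mat1a (1.15 ± 0.34) and Cdo1 (0.31 ± 0.13), with adjusted p-values over all genes of 0.229, 0.258, 0.205, 0.238, 0.208, 0.283, 0.277 and 0.4 in that order.

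Other splits of the arrays were counted for each contrast. For fat level averaged over both oils, 1 of 100 splits of the fat labels within each oil, the real one, gave as many as 199 probe sets and the highest other gave 6, which excludes chance at this share. For the oils averaged over both levels, 1 of 100 splits gave as many as 2120 and the highest other gave 1105, which excludes chance but not the index. For contrasts of 3 arrays against 3, the 10 splits are too few for a share under 0.05: the real split, the 1 split to reach its own count, gave 184 probe sets with corn oil (highest other 8), 38 with olive oil (highest other 0), 744 between oils at 70% fat (highest other 0) and 1704 at 5% fat (highest other 0). The interaction called 0 probe sets, a count that every split reaches by definition, so the 100 of 100 splits that did say nothing about chance. The highest other gave 2120, a structure of the samples in which exchanged oil labels at 1 fat level turn the oil difference into an interaction.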

How the results depend on the processing

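The index covariate, also with an estimated correlation for the lists, and the fit on low-index arrays were added after the data had been seen. The low-value filter and the highest-mean probe set were not run, because centred values hold no level, and the linear-scale alternative did not apply; the trend in eBayes ran on centred means for the same reason. The number of arrays limits the precision. In 17 named genes called for fat level averaged over both oils, 16 kept the call without each array in turn, under each planned setting and with the index; Cyp2e1 was the exception. Without each array in turn 14 of 35 named genes kept the call with corn oil, 7 of 20 with olive oil, 9 of 22 between oils at 70% fat and 20 of 25 at 5% fat. Under the other planned settings 10 of 35, 10 of 20, 13 of 22 and 25 of 25 kept it; a second quantile normalization alone ended 24 calls with corn oil. With the index 10 of 35, 20 of 20, 0 of 22 and 0 of 25 kept it. The cause was not tested for any change below except that 1 value per gene and a 1.5-fold minimum leave fewer items and smaller fits fewer arrays.

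With the index as a covariate the counts of probe sets were 40 for fat with corn oil, 64 with olive oil and 123 averaged. They were 0 for each of the 3 oil contrasts. The fit on low-index arrays left 1 corn oil array at 70% fat, so no count is given for it. A second quantile normalization gave 51 (26 up) with corn oil and 98 with olive oil, and centring each array 22 (4 up) with olive oil. The quantile step made the spread of every array equal. Before it the SD over probe sets ran from 0.28 to 0.42 with 5% corn oil and from 0.22 to 0.38 with 70% corn oil. With olive oil it ran from 0.20 to 0.27 at 5% and from 0.20 to 0.23 at 70% fat. Array weights gave 138 with olive oil, 2632 between oils at 5% fat and 2 for the interaction. Fits on 2 groups gave 53 with corn oil, 97 with olive oil and 334 between oils at 70% fat. With 1 value per gene the counts were 120 with corn oil, 328 and 801 between oils at 70% and 5% fat, 103 for averaged fat level and 1035 for averaged oil. A 1.5-fold minimum gave 370 and 886 between oils, 109 for averaged fat level and 643 for averaged oil.

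Without 1 array the count ran from 59 to 348 with corn oil, 10 to 69 with olive oil, 311 to 1162 between oils at 70% fat and 1115 to 2065 at 5% fat, 0 to 10 for the interaction, 116 to 233 for averaged fat level and 1728 to 2309 for averaged oil. Scd, Pnpla3, Fasn, Fabp5, Slc2a5 and Aldh1a1 kept their fat-level calls with each oil without each array in turn.

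Over 7 contrasts of 29 lists, 42 tests passed by camera; 4 passed with an estimated correlation, 3 with the index and an estimated correlation (the averaged lipogenic list, at adjusted p = 0.0727, being the 1 lost), and without 1 array 39 to 48. List calls were lost without pool 3 of 70% corn oil for oxidative phosphorylation with fat in corn oil (adjusted p = 0.282), oxidation and antioxidant genes between oils at 70% fat (0.222 and 0.365), and antioxidant genes, cytochromes and amino acid catabolism averaged (0.139, 0.207 and 0.0916). With olive oil endoplasmic reticulum stress and endothelial markers lost theirs without pool 3 of 5% olive oil (0.157 and 0.21). The number of arrays whose absence ended the call was 2 for cytochromes with olive oil and between oils at 70% fat, 6 for cholesterol synthesis at 70% fat, 6, 4 and 3 for antioxidant, matrix and hepatocyte lists at 5% fat, 4 and 5 for cytochromes and macrophage markers with averaged fat level, and 7 for amino acid catabolism in the interaction. The correlation of both fat effects was 0.451, 0.391 over every probe set, 0.483 after quantile normalization, and 0.392 to 0.483 without 1 array. Same-numbered pools did not deviate together: 3 of 18 pairs correlated above 0.1, from -0.194 to 0.232, and 11 of 36 comparisons favoured the array's own number. The replicate block gave 221, 37, 650, 1625, 1, 187 and 2053 probe sets for fat with corn oil, with olive oil, oil at 70% and 5% fat, the interaction, averaged fat level and averaged oil.

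Among the lists and named genes called without the index, directions reversed with it as a covariate in oil contrasts, and none of these passed afterwards. At 70% fat these were oxidation genes (adjusted p = 0.69), antioxidant genes (adjusted p = 0.528) and cytochromes (adjusted p = 0.329), and the genes Hadhb, Gsr, Mug1 and Col1a2, with log2 changes of 0.36, 0.0051, 0.20 and -0.0506 (adjusted p of 0.846 or more). At 5% fat they were oxidation genes (adjusted p = 0.307), antioxidant genes (adjusted p = 0.0787), matrix genes (adjusted p = 0.876) and amino acid catabolism (adjusted p = 0.263), and the genes Mug1, Hadhb, Cyp4a1, Cps1, Hnf4a and Col1a2, with log2 changes of 0.53, 0.68, 0.009, 0.0319, 0.22 and -0.0894 (adjusted p of 0.884 or more). Of lists not called without it, cytochromes at 5% fat and oxidative phosphorylation averaged went from down to up (adjusted p = 0.0488 and 0.00377; adjusted p = 0.795 and 0.764 with an estimated correlation as well). Averaged, those called were oxidation genes (adjusted p = 0.489), antioxidant genes (0.179), cytochromes (0.0838) and amino acid catabolism (0.11). With an estimated correlation as well these lists reversed too, with adjusted p of 0.846, 0.846 and 0.734 at 70% fat, 0.795, 0.795, 0.913 and 0.795 at 5% fat and 0.764 for the 4 averaged.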

Other observations

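The tests here were chosen after the values had been seen. Genes of MHC class II presentation, a group not among the lists fixed beforehand, were lower at 70% than at 5% olive oil in 8 of 10 measured members, with a median of -0.27. Ctss, which trims the invariant chain, fell by 0.96 ± 0.16 (adjusted p = 0.0164) and RT1-DMb, a peptide exchange factor, by 0.39 ± 0.08 (adjusted p = 0.0432). RT1-Da was at -0.70 ± 0.15 (adjusted p = 0.0649) and Cd74, the invariant chain, at -0.55 ± 0.14 (adjusted p = 0.152). With corn oil 8 of the 10 were lower too, with a median of -0.06, and limma called 0 of them.

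A hypothesis from these values is that antigen presentation genes are lower with 70% olive oil. With an estimated correlation camera gave p = 0.00584 with olive oil, and p = 0.104 for the difference between the oils, so the data may hold a fall with olive oil but do not show that it differs from corn oil. Markers of macrophages and Kupffer cells, which present antigen, moved further down in the same contrast (9 genes, median -0.42, camera adjusted p = 6.24e-06; adjusted p = 0.133 with an estimated correlation), so fewer or altered presenting cells stay open. The list was chosen on these arrays, Cd74 also belongs to the macrophage list, and RT1 probes can bind related transcripts.

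With pool 2 as the 1 array of 70% corn oil, Scd was at -3.47 against 70% olive oil, Cd36 at -1.20 and Fasn at -1.07. Over all arrays they were at -2.96, -1.25 and -0.99. Acly was at -0.70, Acaca at -0.49, Cd74 at 0.58 and Lyve1 at 0.85, against -0.59, -0.43, 0.69 and 1.09 over all arrays. Hadhb was at -0.20, Mug1 at -0.78 and Mat1a at -0.97, all smaller than the -1.23, -2.47 and -1.46 over all arrays. These values rest on 1 corn oil array, so the spread of that diet is not measured. Over its 3 arrays the SD of Scd was 0.94, against 0.21 with 70% olive oil. The index was not matched either, at 0.16 against -0.41 to -0.23 with 70% olive oil. Of the 1704 probe sets called between oils at 5% fat, 81.2% lay on the corn oil side on this array. Their median difference from 70% olive oil, signed by the direction at 5% fat, was 0.21 on this array. It was 0.42 and 0.41 on pools 1 and 3 of 70% corn oil, which had an index of 0.95 and 1.03. The shares there were 93.7% and 86.3%. The difference was thus smaller on the array with the lower index.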
